A study of Homo sapiens with 5 samples.

How the data were processed

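The data are single-cell RNA libraries of OVCAR5, an established human ovarian carcinoma cell line. Per the labels, 5 libraries were made, and all 5 carry 1 shared description, a mixture of 7 conditions. The conditions are tumor cells from T-cell-treated mice, tumor cells from control mice, and cultured cells without cytokine, with interferon gamma at 100 ng/ml, with TNF alpha at 10 ng/ml, with both cytokines, and with both cytokines followed by the tissue digest, each culture lasting 24 h. Per the labels' protocols, cells were stained with hashtag antibodies, which add a countable DNA tag to every cell of a condition, then pooled, sorted for the CFP reporter and captured on the 10x Genomics 3' platform. The labels give no key from hashtag number to condition.

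The deposited matrix holds whole-number UMI counts, not normalized, for 33538 genes and 7 hashtag features in 3204 barcodes, per the file headers. Per the submitters' processing notes, Cell Ranger 2.1.1 and the GRCh38 build were used, while the matrix header gives software version 3.0.2. Which of these versions wrote the counts is not settled by the sources used here. The rule by which barcodes were kept as cells, the annotation release and the hashtag counting are not given in the sources used here. All barcodes carry 1 suffix, so no cell can be tied to a labelled library, and the matrix was treated as 1 sample. Leaving out single libraries was therefore not run.

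Gene lists, tests, settings, a first set of alternatives and the rule for named genes were fixed before the data were examined. A further 18 alternatives were added after the data were seen. Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs. A hashtag was called when it held at least 80% of a barcode's hashtag counts and at least 10 counts. Hashtags stay named by number, and the contrasts between conditions in the design were not run, because a condition is not to be read from expression. UMIs were summed over the called cells of each hashtag and scaled to 1000000 UMIs (CPM) with exact Poisson intervals at the 95% level. Each hashtag is 1 sample, so no test was run, and every interval covers counting error only. Each hashtag was compared with the summed UMIs of the other hashtags, for all 7 alike, by the ratio of CPM with its exact conditional interval. The fixed rule did not say against what a hashtag is compared. Pairs had been looked at first, and this form was chosen after the data were seen, because choosing pairs by their values would pick samples for looking affected. All 21 pairs were computed. A member of a list counts as higher or lower when its ratio is over 1.5 or under 1/1.5 and the interval excludes 1.

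The rule for named genes takes the 4 members of each list with most UMIs, and, per contrast among genes with at least 100 UMIs, the 12 highest and 8 lowest ratios and up to 4 members per list farthest from 1. It also takes 8 readout genes whatever their values, and 10 genes for the joint score ranges. The text names those it can describe. There were 19 lists: interferon response, NF-kB response, shared by both cytokines, S phase, G2 and M phase, hypoxia and glycolysis, dissociation and immediate early, unfolded protein response, cholesterol synthesis, epithelial and carcinoma identity, mesenchymal, matrix remodelling and inflammation proteases, metallothionein, cell death, housekeeping, T cell, myeloid and B cell, fibroblast and endothelial, and erythroid. Where 2 gene identifiers share a symbol, the identifier with more UMIs stands for it. Reads of near-identical genes, such as HLA and metallothionein genes, can be split between copies, so their single values are uncertain. Coordinates are from GENCODE annotation of GRCh38, in which 33456 of the 33538 gene identifiers were found.

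A list score is the mean over genes of the z score of log1p(counts per 10000), computed from the deposited counts. Cells were ranked on the odd-numbered members in alphabetical order and divided where the parts of a 2-component Gaussian mixture are equally likely. The remaining members were the readout. Scores were correlated across cells beside 1000 pairs of random lists matched on mean level. Clusters are Leiden clusters, named only from fixed markers, made also without the genes of the interferon, NF-kB and shared lists. Cycle shares are shares of cells with a list score above 0 after each cell was thinned to 5000 UMIs. Scrublet, at an expected rate of 6%, called 9 of 1598 cells doublets; these were kept in the main results and left out in an alternative. Alternatives to the cell filter, hashtag call, scaling, depth, score and clustering were run. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 and scikit-learn 1.9.0 were used. The ratio rule was tested on simulated Poisson counts drawn from the pooled profile, with 200 changed genes among 11612. For Hashtag 6, with most UMIs, 100% of 50 genes with a true fold of 2 were called. For Hashtag 2, with fewest UMIs, 72.0% were called, against 56.0% of 50 genes with a true fold of 0.5 and 84.0% with 0.25, and 97.8% of unchanged genes stayed without a call. The simulation held no spread between cells beyond counting error, so these rates need not carry over to the deposited counts.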

Results

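The matrix held 3204 barcodes with a median of 17732 UMIs, from a pool of OVCAR5 cells in 7 conditions. Of these, 1598 passed the cell filter, with a median of 53170 UMIs and 6524 genes, and 1488 barcodes exceeded the mitochondrial limit. A single hashtag was called in 1339 passing cells, and 259 had no call. Hashtags 1 to 7 held 245, 65, 155, 152, 177, 346 and 199 passing cells, with median UMIs of 17905, 16623, 65794, 62428, 68334, 58284 and 57011. The share of called barcodes over the mitochondrial limit was 76.1% for Hashtag 1 and 80% for Hashtag 2, and lay between 12.8% and 23.3% for the other hashtags. Summed UMIs ran from 1149668 for Hashtag 2 to 20028811 for Hashtag 6. The study asked how tumor cells respond to interferon gamma, TNF alpha, their combination and T cells. Without a hashtag key that question cannot be put to these counts, so the values below describe numbered hashtags, each a single sample without replicates.

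CXCL10, a chemokine that draws T cells, ranged over hashtags from 39.2 CPM in Hashtag 3 to 8083 CPM in Hashtag 6. It stood at 1111 CPM in Hashtag 1, 65.2 in Hashtag 2, 232 in Hashtag 4, 43.4 in Hashtag 5 and 7570 in Hashtag 7. IDO1, which degrades tryptophan, was at 836, 27.0, 22.9, 2965, 24.5, 3414 and 3833 CPM in Hashtags 1 to 7. HLA-DRA, an MHC class II chain, was highest in Hashtag 1 at 288 CPM (Poisson interval 272 to 304) and lowest in Hashtag 3 at 1.94 CPM. CD274, the gene of PD-L1, ranged from 0.870 CPM (0.0220 to 4.85) in Hashtag 2 to 74.1 CPM (70.4 to 78.0) in Hashtag 6. The adhesion gene ICAM1 was at 124, 44.4, 17.2, 150, 133, 532 and 543 CPM. The neutrophil chemokine CXCL8 was at 107, 113, 2.62, 2.24, 227, 135 and 182 CPM. CCL20, a ligand of CCR6, reached 17.6 CPM in Hashtag 7, and IL6, a cytokine gene, reached 23.2 CPM there. On GRCh38, the protein-coding gene CXCL10 spans chromosome 4 from 76021117 to 76023497, and IDO1 spans chromosome 8 from 39902275 to 39928444.

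**Figure D1:**
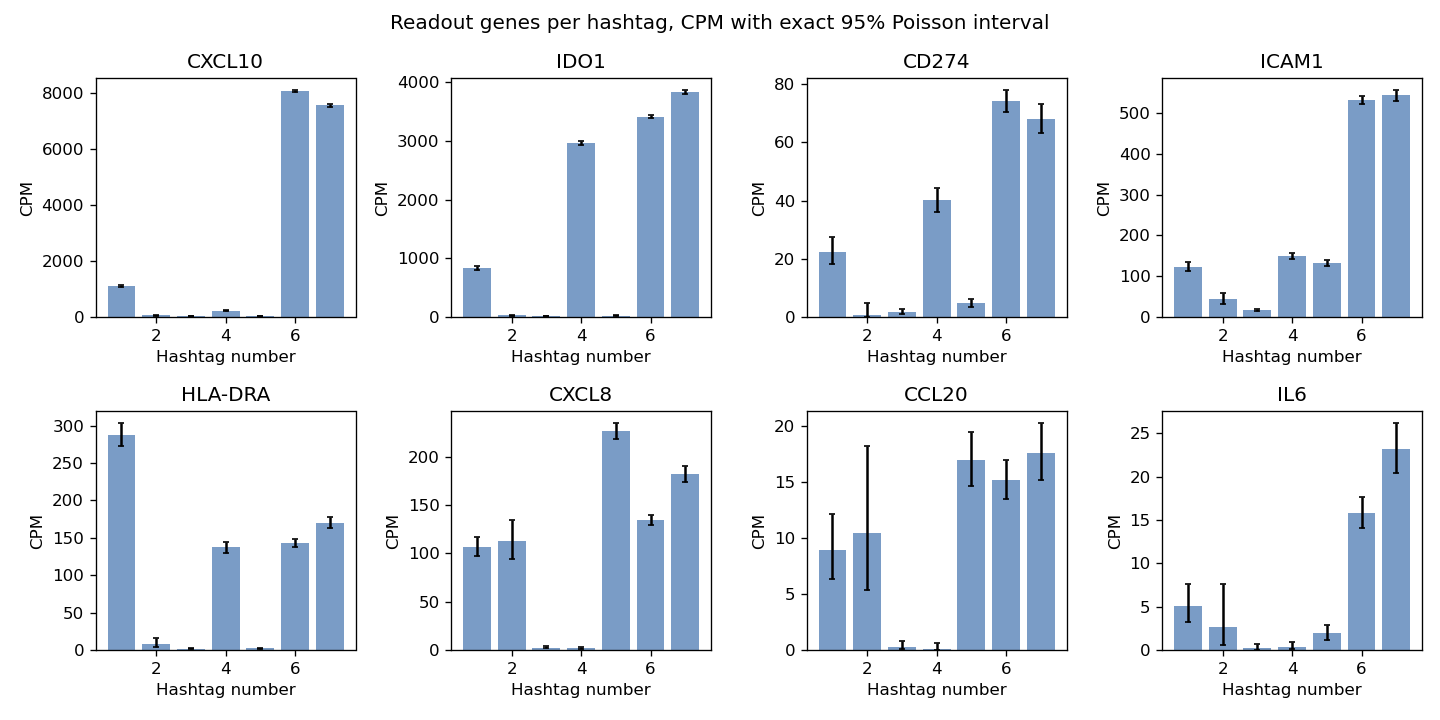
Bars give CPM of 8 readout genes (vertical axes, linear) in each numbered hashtag (horizontal axes), and lines give exact 95% Poisson intervals, which cover counting error only. CXCL10 is highest in Hashtag 6 at 8083 CPM, and HLA-DRA in Hashtag 1 at 288 CPM. Summed levels do not show how many cells carry a gene.

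The interferon response list, genes of antigen presentation and antiviral defence, had 67 measured members. Against the other hashtags together, 58 were higher in Hashtag 6, 43 in Hashtag 7, 29 in Hashtag 1 and 24 in Hashtag 4. In Hashtags 3 and 5 all 67 were lower, and in Hashtag 2 there were 56 lower members. Hashtag 1 also had 8 lower members, and Hashtag 4 had 1. B2M, the light chain of MHC class I, was at 9045, 3291, 1660, 6073, 2241, 6758 and 6629 CPM in Hashtags 1 to 7. GBP1, a guanylate-binding protein, was at 6.12 CPM in Hashtag 3, 11.4 in Hashtag 5 and 13.0 in Hashtag 2. These counts move with the makeup of the other side, and with a 95% hashtag call the higher members numbered 5 in Hashtag 4, 21 in Hashtag 6 and 5 in Hashtag 7. The balance in Hashtag 4 then turned, with 7 lower members, but that call left it 18 of its 152 cells. Hashtags 1, 6 and 7 kept 210, 220 and 167 cells, so the makeup of the other side changed too. After thinning, 38 members were higher in Hashtag 6.

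The NF-kB response list, genes of inflammatory signalling, had 52 members in the matrix, 51 of them with UMIs in at least 10 cells. Of the 52, 28 were higher and 1 lower in Hashtag 7, 26 and 2 in Hashtag 6, and 18 and 12 in Hashtag 5. Hashtags 3 and 4 each had 46 lower members and 0 higher. Hashtag 1 had 12 higher and 19 lower, and Hashtag 2 had 11 higher and 18 lower. NFKBIA, the inhibitor that NF-kB induces, was at 430, 398, 41.3, 77.7, 506, 731 and 717 CPM. LTB, a TNF family member, was at 123 CPM in Hashtag 5 against 12.7 CPM in the others, a ratio of 9.69 (8.86 to 10.6). In Hashtag 4, LTB had only 1 UMI, or 0.107 CPM against 37.1 CPM in the others, a ratio of 0.00288 (7.29e-05 to 0.0161). PTX3, a soluble pattern receptor, was 3.45 times as high in Hashtag 5 as in the others (3.33 to 3.57). With a 95% hashtag call, which left 35 of the 177 cells of Hashtag 5, higher members numbered 12 in Hashtag 7 and 14 in Hashtag 6. In Hashtag 5 they numbered 6, and the lower members stayed at 12, so the balance turned. With 10 CPM added, higher members numbered 16 in Hashtag 7 and 10 in Hashtag 5. Under the stricter filter 17 were higher in Hashtag 6 and 12 lower in Hashtag 1.

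The list shared by both cytokines had 28 measured members, of which 23 were higher in Hashtag 6 and 21 in Hashtag 7, with 1 lower in each. All 28 were lower in Hashtag 3 and 21 in Hashtag 5, with 0 higher. Lower members numbered 22 in Hashtag 2, 16 in Hashtag 4 and 14 in Hashtag 1, against 1, 1 and 5 higher. The member farthest from 1 in Hashtag 1 was higher there: LCN2, an iron-binding defence protein, at 1078 CPM, with 959 CPM in Hashtag 2 and at most 72.4 CPM in the others. With a 95% hashtag call 15 and 9 were higher in Hashtags 6 and 7, and under the stricter filter 7 were lower in Hashtag 1. CXCL9, a ligand of CXCR3 like CXCL10, was at 869 CPM in Hashtag 6 and 753 CPM in Hashtag 7, and at most 43.4 CPM in the other hashtags. IL32, a cytokine gene, was at 3004 CPM in Hashtag 6 and 2958 CPM in Hashtag 7, and between 29.1 and 361 CPM in the other hashtags. Over the 21 pairs of hashtags, the number of shared members that differed ran from 0 to 27.

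Hashtags 1 and 2 had more of the epithelial and carcinoma identity list, with 19 and 20 of 20 members higher. KRT19, a keratin of simple epithelia, was at 2103 and 2116 CPM there, against 135 to 447 CPM in the other hashtags. AGR2, a secretory-pathway disulfide isomerase, was at 1180 and 1750 CPM in Hashtags 1 and 2, and at most 40.9 CPM in the others. CEACAM5, an epithelial adhesion protein, was at 22.7 and 20.0 CPM there, and PIGR, the polymeric immunoglobulin receptor, at 26.5 and 18.3 CPM. Cells of these hashtags were unlike in this list. Cluster 8, with 62 cells of Hashtag 1 and 19 of Hashtag 2, held it at 18378 CPM, and cluster 4, with 156 and 39, at 8266 CPM. The mesenchymal list was at 1411 CPM in cluster 8 and 5214 CPM in cluster 4. Lower members of the list numbered 10, 15, 11, 15 and 13 in Hashtags 3 to 7, against 2, 0, 1, 0 and 0 higher. With 10 CPM added they numbered 5 and 7 in Hashtags 3 and 4, and with the other hashtags weighted equally 18 in Hashtag 5. The other side of these comparisons holds Hashtags 1 and 2, so high levels there alone can make a member lower. The member CDH1 was lower in Hashtags 3 and 4, at 1.94 and 2.03 CPM. It was nevertheless above its 0.0835, 0.250 and 0.0913 CPM in Hashtags 5, 6 and 7. The shallow depth and high mitochondrial share of Hashtags 1 and 2 go with their high levels of this list.

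The dissociation and immediate early list, genes switched on within minutes of stress, had 16 of 25 members higher in Hashtag 1 and 16 in Hashtag 2, with 3 lower in each. Their high mitochondrial share and low depth go with these values too. DUSP1, a phosphatase of MAP kinases, was at 968, 973 and 567 CPM in Hashtags 1, 2 and 7, and at most 62.4 CPM in the others. HES1, a Notch target, was at 41.8, 73.1 and 99.0 CPM in Hashtags 1, 2 and 7. Hashtags 3, 4, 5 and 6 had 14, 13, 11 and 12 lower members, and Hashtag 6 had 1 higher. Here too the other side holds Hashtags 1 and 2, whose high levels alone can make members lower. Hashtag 7 had 4 higher and 3 lower, a balance that turned under 5 settings, for example to 2 higher and 12 lower with the other hashtags weighted equally. That weighting gave 17 lower in Hashtag 5.

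Members of the G2 and M phase list were lower in Hashtags 1, 2, 6 and 7, numbering 25, 27, 17 and 25 of 29, and 28 were higher in Hashtag 3. TOP2A, the mitotic topoisomerase, was at 157, 91.3, 505, 398, 355, 190 and 158 CPM in Hashtags 1 to 7. Of the 26 members of the S phase list, 23 were lower in Hashtag 1 and 18 in Hashtag 2, with at most 2 passing in any other hashtag in this comparison alone. Higher S members in Hashtags 3, 4 and 5 numbered 8, 9 and 10 with the other hashtags weighted equally, 12, 9 and 13 after thinning, and 7, 16 and 14 with a 95% hashtag call. Higher G2 and M members numbered 1 in each of Hashtags 4 and 5, but 19 and 11 with equal weights and 24 and 25 with a 95% call. With that call, lower G2 and M members in Hashtags 1, 2, 6 and 7 numbered 16, 15, 0 and 4, and the 17 of Hashtag 6 became 3 with equal weights. Under the stricter filter, 8 S and 7 G2 and M members were lower in Hashtag 1. After thinning, the share of cells with a G2 and M score above 0 was 14.5% in Hashtag 1 (exact binomial interval 10.0% to 20.0%), 11.9% in Hashtag 2, 76.8% in Hashtag 3, 61.2% in Hashtag 4, 64.4% in Hashtag 5, 38.8% in Hashtag 6 and 31.2% in Hashtag 7. Unthinned, those shares were 14.3%, 15.4%, 81.3%, 73.0%, 70.6%, 43.1% and 37.7%. The S shares after thinning were 7.73%, 11.9%, 67.7%, 65.8%, 65.5%, 34.9% and 46.4%, and unthinned 8.57%, 9.23%, 81.9%, 75%, 71.2%, 39.9% and 47.2%. Thinning left out 38 cells of Hashtag 1, 6 of Hashtag 2, 3 of Hashtag 5, 8 of Hashtag 6 and 7 of Hashtag 7. Free RNA can enter these scores, and phase scores alone do not show cycling.

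**Figure D2:**
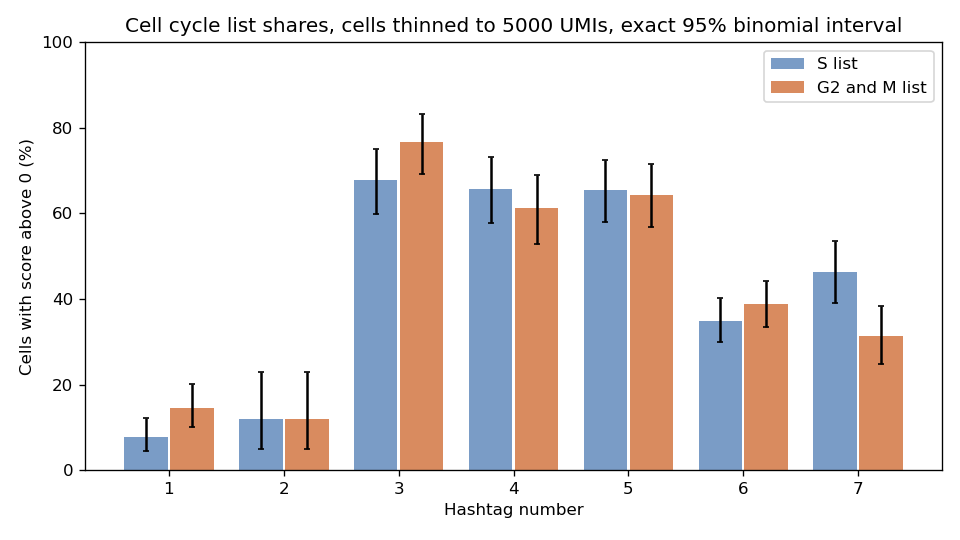
Bars give the percentage of cells (vertical axis) whose S or G2 and M list score is above 0 in each numbered hashtag (horizontal axis) after thinning to 5000 UMIs, with exact 95% binomial intervals. The G2 and M share is 76.8% in Hashtag 3 and 11.9% in Hashtag 2.

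Hypoxia and glycolysis members, 29 in all, were lower in Hashtag 1 (17, with 4 higher), Hashtag 3 (10) and Hashtag 5 (8), and Hashtag 2 had 8 higher and 7 lower, a balance that turned under 4 settings. LDHA, which makes lactate, was at 1209 CPM in Hashtag 1 against a highest level of 3162 CPM in Hashtag 7. Of 22 cell death members, 16 were lower in Hashtag 3 and 10 in Hashtag 5, with 0 higher, and 11 were lower and 2 higher in Hashtag 2. In Hashtag 6, 9 were higher and 1 lower, in Hashtag 7, 7 and 1, and in Hashtag 1, 6 and 4. The balance turned in Hashtag 7 with a 95% call (0 higher and 1 lower), and in Hashtag 1 with that call (4 and 8), without the cell filter and with size factors (5 and 7 in both). TNFSF10, the death ligand TRAIL, was at 280 CPM in Hashtag 1 and 8.51 CPM in Hashtag 5. In Hashtags 1 and 2, 7 of 18 unfolded protein response members were higher and 1 lower. Of 18 cholesterol synthesis members, 6 were higher and 0 lower in Hashtag 2, and 4 were higher and 3 lower in Hashtag 1, a balance that turned under 4 settings. Of 16 mesenchymal members, 13 with UMIs in at least 10 cells, 7 were lower in Hashtag 4. In Hashtag 1, 6 were higher and 4 lower, a balance that turned under 5 settings. Of 14 matrix and protease members, only 9 had UMIs in at least 10 cells. Of the 14, 7 were lower in each of Hashtags 3 and 4, with 2 and 0 higher. At most 3 of 8 metallothionein members and 4 of 13 housekeeping members passed in any hashtag. GAPDH, a glycolytic enzyme of the housekeeping list, was nevertheless at 3002 CPM in Hashtag 1 and 6167 CPM in Hashtag 7.

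Ratios are relative to a median log2 ratio of all ranked genes that ran from -0.19 for Hashtag 7 to 0.14 for Hashtag 2. The SD of those log2 ratios ran from 0.516 in Hashtag 7 to 0.973 in Hashtag 2, and was 0.940 in Hashtag 1. The share of all ranked genes passing the rule was not counted. Lists with modest counts, such as unfolded protein and cholesterol members in Hashtags 1 and 2, may therefore not differ from genes at large. The same limit holds for other lists in these hashtags, where the SD was widest. Examples are NF-kB members, with 12 higher and 19 lower in Hashtag 1 and 11 and 18 in Hashtag 2. Further examples are mesenchymal members in Hashtag 1 (6 and 4) and cell death members in Hashtag 2 (2 and 11). Without the share for all ranked genes, these counts do not set a list apart. With the median log2 ratio of each contrast set to 0, the interferon members higher in Hashtag 7 numbered 58, and the lower G2 and M members 5 in Hashtag 6 and 15 in Hashtag 7. Hypoxia members then split into 12 higher and 1 lower in Hashtag 6 in place of 7 and 2, and 8 and 1 in Hashtag 7 in place of 3 and 2. Unfolded protein members in Hashtag 2 split into 6 and 3 in place of 7 and 1, and cholesterol members into 4 and 2 in place of 6 and 0. In Hashtag 1, cell death members split into 5 and 6 in place of 6 and 4, and cholesterol members into 3 and 4 in place of 4 and 3. In Hashtag 3, cholesterol members split into 0 and 5 in place of 1 and 4, and unfolded protein members into 1 and 2 in place of 1 and 1. In Hashtags 6 and 7, unfolded protein members split into 1 and 0 in place of 0 and 1.

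Across all 1598 cells, interferon and NF-kB scores had a Pearson r of 0.407 and a Spearman rho of 0.432. Random lists matched on level gave a mean r of 0.693 (95% of them between 0.606 and 0.761) and a mean rho of 0.520 (0.376 to 0.653), so here the r lay below the random range and the rho inside it. That position changed with the setting, each time beside 200 random pairs. After thinning the rho of 0.330 lay above the random range (-0.0588 to 0.134). Without the cell filter the rho of 0.648 lay below it (0.755 to 0.872), as did 0.374 with a 30% mitochondrial limit (0.386 to 0.693). On residuals from cycle scores and depth, for which no random range was made, the rho was 0.260. Within hashtags r ran from 0.0480 in Hashtag 2 to 0.541 in Hashtag 7. Cells are not replicates, so these are descriptions.

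**Figure D3:**
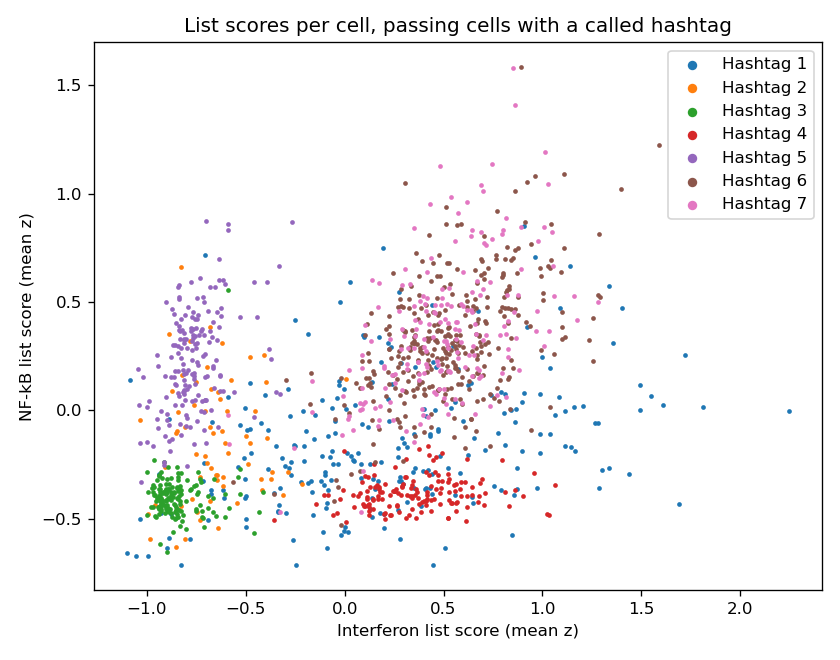
Each point is a passing cell with a called hashtag (colours), placed by its interferon list score (horizontal axis, mean z) and NF-kB list score (vertical axis, mean z). Across all passing cells the Pearson r is 0.407.

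In the high range of the interferon score, all 33 members held out of the ranking were higher, and 26 of 28 shared members. CXCL9 was at 553 CPM in the high range and 4.53 CPM in the low range, and HLA-DPA1, an MHC class II chain, at 86.4 and 0.936 CPM. The range held 1039 cells (65.0%, exact binomial interval 62.6% to 67.4%), with 54 cells within 0.1 of the dividing score. By hashtag it held 85.3%, 16.9%, 1.29%, 100%, 3.95%, 99.1% and 98.5% of cells. In the same range 24 of 29 G2 and M members were lower, but this did not hold hashtag by hashtag. Hashtag 4, with 100% of cells in the range, held that list at 3879 CPM. Hashtag 5, with 3.95%, held it at 3773 CPM. Median UMIs were 52587 in the high and 55423 in the low range.

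In the high range of the NF-kB score, 23 of 25 held-out members were higher and 27 of 28 shared members. CSF2, the GM-CSF gene, was at 81.0 CPM in the high range against 2.45 CPM in the low range, a ratio of 33.0 (25.7 to 43.0), and CCL2, a monocyte chemokine, at 133 against 3.35 CPM. The range held 957 cells (59.9%, 57.4% to 62.3%), with 212 within 0.1 of the dividing score. The binomial interval does not cover the choice of score or filter: the share was 39.3% without the cell filter and 98.2% with the score as a share of UMIs. After thinning the parts of the mixture lay too close (1.78 pooled SDs) for a division there, and the 33.4% of cells with the highest scores were taken instead, a share fixed by that rule. By hashtag it held 45.7%, 55.4%, 0.645%, 5.26%, 97.2%, 97.4% and 97.0% of cells. As in the high interferon range, G2 and M members were lower here, 19 of 29 with 0 higher. Again this did not hold hashtag by hashtag. Hashtag 5, with 97.2% of cells in the range, held that list at 3773 CPM. Hashtag 4, with 5.26%, held it at 3879 CPM. Of 20 epithelial members 11 were lower and 1 higher. Median UMIs were 56586 in the high and 41035 in the low range, so depth goes with this range. With that score as a share of UMIs, 5 of the 25 held-out members were higher.

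Cells high in both scores numbered 704, against 335 high only for interferon, 253 high only for NF-kB and 306 low in both. Of the 28 shared members, 17 were higher in the range high in both than in each single range, against 11 under a stricter cell filter and 6 with scores taken as shares of UMIs. CXCL10 was at 7132 CPM there, 307 CPM in the interferon range and 46.9 CPM in the NF-kB range, so it was 23.3 times the higher of these (22.6 to 24.0). CXCL9 was 25.0 times as high (22.7 to 27.7), CXCL11 was 15.3 times and CCL5, another T-cell chemokine, 13.9 times (10.3 to 19.1). IDO1 was 1.28 times as high (1.27 to 1.30). LCN2 was lower, at 146 against 237 CPM. Of the 704 cells, 335 were called Hashtag 6, 192 Hashtag 7 and 102 Hashtag 1, so ranges follow hashtags.

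The cells fell into 10 clusters, of which 3 could be named. Cluster 4, dissociation and immediate early-like, held 204 cells, of which 156 were called Hashtag 1 and 39 Hashtag 2. Cluster 9 held 33 cells and was named interferon response-like from 3 markers, but its interferon list level of 31358 CPM was below those of clusters 1, 4 and 2, at 38884, 33229 and 31624 CPM. Cluster 10, fibroblast and endothelial-like, held 27 cells. Without the genes of the interferon, NF-kB and shared lists there were 9 clusters. The largest, 385 cells, held 151 cells of Hashtag 3 and 171 of Hashtag 5, with an interferon list level of 5788 CPM. Clusters 2 and 4 of that set held 173 and 121 cells of Hashtag 6, at interferon levels of 39171 and 31569 CPM and G2 and M levels of 687 and 3613 CPM. Only listed genes were left out, and unlisted genes that go with the scores remained. ACOD1 was among the leading genes of cluster 2 and IFNL1 among those of cluster 4. Both also had some of the highest ratios in the high interferon range. The interferon levels are therefore not independent of how these clusters were made. A cluster made mostly of a single hashtag may be that sample and not a type.

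T cell markers were sparse, with 181 UMIs over 1598 cells (2.35 CPM), of which LCK, a T-cell kinase, gave 96. Of the cells, 9.82% had a UMI of that list (8.41% to 11.4%). The myeloid and B cell list stood at 76.4 CPM, led by CD68, a lysosomal protein, with 4184 of 5895 UMIs. Its member LYZ, lysozyme, was at 120 CPM in Hashtag 1 and 161 CPM in Hashtag 2, and at most 1.71 CPM in the others. By cluster, the whole list was highest in cluster 8, at 447 CPM, against 93.6 CPM in cluster 4. Cluster 8 also had the highest level of the epithelial list, at 18378 CPM, so these values need not mark myeloid cells. The fibroblast and endothelial list stood at 32.8 CPM, and 9 of its 14 members had UMIs. Of the 14, 6 were higher in Hashtag 1. COL1A2, a fibrillar collagen chain, was at 30.5 CPM there against 0.0941 CPM in the others, and 8 of the 27 cells of cluster 10 were called Hashtag 1. Without those 8 cells the list in Hashtag 1 fell from 85.9 to 19.7 CPM. Its members were not counted again without them. The log2 ratio of COL1A2 was 8.34, and 5.16 without cells under 5% mitochondrial UMIs. The erythroid list had 3 UMIs.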

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

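In this part, the tests of depth and of hashtag calls in Hashtag 1, that of free RNA in the collagen-rich cluster, and the comparison of failing with passing barcodes by hashtag, were chosen after the result was seen. In barcodes that the main comparison between hashtags left out, some lists stood above their level in all called passing cells. The fibroblast and endothelial list was at 204 CPM in passing barcodes without a called hashtag and 23.1 CPM in barcodes failing the filter, against 10.4 CPM in called passing cells. The myeloid and B cell list was at 169 CPM in failing barcodes against 76.7 CPM, led by LYZ with 1815 of 3313 UMIs. The T cell list was at 3.62 CPM in failing barcodes against 2.24 CPM, a ratio of 1.61 whose exact interval excludes 1, with LCK giving 53 of 71 UMIs. Failing barcodes had another mix of hashtags, with 58.0% of their UMIs from Hashtag 1 and 15.4% from Hashtag 2. Passing cells mixed like the called failing barcodes would hold the T cell list at 4.56 CPM, the myeloid and B cell list at 206 CPM and the fibroblast list at 57.3 CPM. The called failing barcodes held 3.64, 170 and 20.8 CPM, so the T cell and the myeloid and B cell lists were not above that mix. For the fibroblast list this rests on 9 passing barcodes of the collagen-rich cluster described next, since without them the mix would be below the failing barcodes. In Hashtag 1, without its 8 such barcodes, passing cells held 19.7 CPM against 26.8 CPM in failing barcodes, a ratio of 1.36 (1.07 to 1.75). Within single sets and with all passing cells, failing barcodes were above passing ones, with an interval excluding 1, for the myeloid list in Hashtag 2 (284 against 243 CPM) and in uncalled barcodes (159 against 74.1 CPM), and for the fibroblast list in Hashtag 2 (18.5 against 9.57 CPM).

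The fibroblast list in uncalled barcodes traced to a cluster of 27 barcodes with a median of 2560 UMIs, 1.00% mitochondrial UMIs and 22 hashtag counts. It held 98.7% of all COL1A2 UMIs in passing barcodes, at 11735 CPM, and 99.7% of those of COL3A1. Droplets with only free RNA of the pool would carry CXCL10 near the pool level, but its CPM was 0.115 times that of all passing cells. Whether these are human cells or host cells whose RNA was read on the human genome was not tested, and the cells had been sorted for the CFP reporter. No biological explanation was tested.

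The interferon score had an SD of 0.494 in Hashtag 1 after thinning, against 0.240 in the next widest, Hashtag 6. Depth as the whole cause is argued against by that thinned ratio of 2.06. Cells of other hashtags taken for Hashtag 1 are argued against by a ratio of 2.05 when the hashtag had to hold 95% of counts. Damage is argued against by a Spearman rho of -0.190 between score and mitochondrial share, although cells over the limit of 20% were left out. No biological explanation was tested, since the hashtag has no condition.

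CXCL10 in Hashtags 2, 3 and 5, chosen after their values were seen, was at 65.2, 39.2 and 43.4 CPM, and 67.7%, 87.7% and 91.5% of their cells had a UMI, or 27.1%, 15.5% and 18.4% after thinning. A few wrongly called cells are argued against, since the 5% of cells with most CXCL10 UMIs held as little as 15.8% of them and at most 17.3%. Those shares were between 0.785 and 1.14 times the Poisson share at each cell's depth, although the 15.9% of Hashtag 3 exceeded the 97.5% point of its Poisson draws. The draws let CXCL10 rise with a cell's depth, as even expression would, while free RNA need not. They therefore cannot tell free RNA, which may account for the level, from even expression. In Hashtag 3, CXCL10, IDO1 and CXCL9 were at 0.00899, 0.00935 and 0.00816 times the other hashtags together. They were at 0.00968, 0.00971 and 0.00932 times in Hashtag 5, and 0.0173, 0.0127 and 0.0200 in Hashtag 2. For these genes, the near-equal fractions of Hashtags 3 and 5 go with free RNA of the pool, and low expression does not predict them. There HLA-DRA, at 0.0153 and 0.0179 times, and CD274, at 0.0367 and 0.0983, did not share them. CXCL11 and HLA-DPA1 were at 0.0114 and 0.0130 times in Hashtag 5, and GBP1 was higher in Hashtag 5 than in Hashtag 3. The fractions were therefore not common to all genes low in these hashtags. Low and even expression predicts the same spread and was not excluded.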

How the results depend on the processing

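Followed through the settings were 63 results, the member counts of 7 lists in 7 hashtags and values of the pool, scores, clusters and cell types, and 95 of their values moved. Counts and shares cannot change sign, so the balance of higher over lower members was followed too, a check chosen after the data were seen. It turned in 42 of 1501 cases over all lists, and in 7 of 553 for the 7 lists: interferon in Hashtag 4 (5 higher and 7 lower) and NF-kB in Hashtag 5 (6 and 12) with a 95% call, and immediate early in Hashtag 7 with that call (1 and 10), with equal weights (2 and 12), and without the cell filter, with a 30% mitochondrial limit and after thinning (each 2 and 10). Cases with as many higher as lower members in the main setting were counted but could not turn, such as the S list in Hashtag 3. Higher S members appeared there under other settings, so the rates of turning overstate stability. No paired analysis was possible because no number pairs samples. Leaving out single libraries and alternatives for the contrasts between conditions were not run, since no cell can be tied to either. Under the stricter filter only Hashtags 1 and 6 kept at least 10 cells, so other hashtags have no value there. Changes of the call or filter also change the makeup of the other hashtags. Apart from that, the cause was not tested. For list members and single genes, every setting but the 2 hashtag calls was chosen after the data were seen, as were the 30% limit and the removal of cells under 5% mitochondrial UMIs for scores.

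For 89 log2 ratios of single genes, 593 values under other settings stayed the same, 388 moved beyond counting error and 3 reversed. Counting error is narrow for genes with many UMIs, so small moves count there. Under the stricter filter, CD274 in Hashtag 1 reversed to 0.13 and IL6 in Hashtag 6 to -0.27. With a 95% call, HLA-DRA in Hashtag 6 reversed to -0.19.

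Cells numbered 3204 without the filter and 79 under the stricter filter, and called cells 2786 and 62, or 713 with a 95% call. The 95% call left 210, 31, 32, 18, 35, 220 and 167 cells in Hashtags 1 to 7.
With a 95% hashtag call, higher interferon members numbered 5, 21 and 5 in Hashtags 4, 6 and 7, higher NF-kB members numbered 6, 14 and 12 in Hashtags 5, 6 and 7, higher shared members numbered 15 and 9 in Hashtags 6 and 7, higher immediate early members numbered 1 in Hashtag 7, higher S members numbered 7, 16 and 14 in Hashtags 3, 4 and 5, lower S members numbered 1 in Hashtag 6, lower G2 and M members numbered 16, 15, 0 and 4 in Hashtags 1, 2, 6 and 7 and higher G2 and M members numbered 24 and 25 in Hashtags 4 and 5. With a 60% call, higher S members numbered 1 in Hashtag 4. Without the cell filter, higher immediate early members numbered 2 in Hashtag 7, higher S members numbered 9, 8 and 13 in Hashtags 3, 4 and 5, lower S members numbered 0 in Hashtag 6, higher G2 and M members numbered 20 and 19 in Hashtags 4 and 5 and lower G2 and M members numbered 1 and 12 in Hashtags 6 and 7. Under the stricter filter, lower NF-kB members numbered 12 in Hashtag 1, higher NF-kB members numbered 17 in Hashtag 6, lower shared members numbered 7 in Hashtag 1, lower S members numbered 8 and 10 in Hashtags 1 and 6 and lower G2 and M members numbered 7 and 2 in Hashtags 1 and 6. With a 30% mitochondrial limit, higher immediate early members numbered 2 in Hashtag 7, higher S members numbered 7, 2 and 7 in Hashtags 3, 4 and 5, lower S members numbered 1 in Hashtag 6, higher G2 and M members numbered 12 and 10 in Hashtags 4 and 5 and lower G2 and M members numbered 7 in Hashtag 6. Scaled by size factors, the median ratio of each hashtag to the geometric mean of all 7, which differ from setting the median of each contrast to 0, higher S members numbered 1 in Hashtag 5, lower S members numbered 1 in Hashtag 6, higher G2 and M members numbered 0 in Hashtag 5 and lower G2 and M members numbered 7 and 16 in Hashtags 6 and 7. With 10 CPM added, higher NF-kB members numbered 10 and 16 in Hashtags 5 and 7, lower epithelial members numbered 5 and 7 in Hashtags 3 and 4, higher S members numbered 0 in Hashtag 5, lower S members numbered 0 in Hashtag 6, higher G2 and M members numbered 0 and 0 in Hashtags 4 and 5 and lower G2 and M members numbered 8 in Hashtag 6. Thinned to 5000 UMIs, higher interferon members numbered 38 in Hashtag 6, higher immediate early members numbered 2 in Hashtag 7, higher S members numbered 12, 9 and 13 in Hashtags 3, 4 and 5, lower S members numbered 1 in Hashtag 6, higher G2 and M members numbered 19 and 16 in Hashtags 4 and 5 and lower G2 and M members numbered 9 in Hashtag 6. Without doublets, higher G2 and M members numbered 2 in Hashtag 4. With the other hashtags weighted equally, lower immediate early members numbered 17 in Hashtag 5, higher immediate early members numbered 2 in Hashtag 7, lower epithelial members numbered 18 in Hashtag 5, higher S members numbered 8, 9 and 10 in Hashtags 3, 4 and 5, lower S members numbered 1 in Hashtag 6, higher G2 and M members numbered 19 and 11 in Hashtags 4 and 5 and lower G2 and M members numbered 3 in Hashtag 6. 

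The rho of the scores was 0.648 without the cell filter, below its random range of 0.755 to 0.872, and 0.330 after thinning, above its random range of -0.0588 to 0.134. It was 0.260 on residuals from cycle scores and depth, with no random range. Held-out NF-kB members higher in the high range numbered 5 with the score as a share of UMIs. Shared members above both single ranges numbered 11 under the stricter filter and 6 with shares of UMIs. Clusters numbered 5 at resolution 0.2, and without cytokine genes 5 at 0.2 and 14 at 1.0. Without the filter, 6.93% of cells had a T cell UMI, 57.4% a myeloid and B cell UMI and 20.0% a fibroblast and endothelial UMI.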

Other observations

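No test was run for this part, and its last values were picked out after the data were seen. FOXJ1, the master regulator of motile cilia, was at 23.4 CPM in Hashtag 1, 3.48 CPM in Hashtag 2 and at most 0.0999 CPM in the others. S100A9, a calcium-binding protein of inflamed epithelium and neutrophils, was at 83.7 and 47.8 CPM in Hashtags 1 and 2, and at most 0.668 CPM in the others. BCL2A1, a survival gene that NF-kB induces, was at 2.00, 0.870, 0.486, 2.13, 20.3, 57.8 and 72.3 CPM in Hashtags 1 to 7. IL7R, an interleukin receptor chain, was at 4.23 and 1.74 CPM in Hashtags 1 and 2, and at least 20.1 CPM in the others. In Hashtag 3, CYP1A1, a target of the aryl hydrocarbon receptor, was at 8.65 CPM against 0.673, and AKR1B10, an aldo-keto reductase, at 61.9 against 13.6 CPM. IL7, a lymphocyte survival cytokine, was at 19.4 CPM in Hashtag 4 against 6.62 CPM. ACOD1, which makes itaconate, was at 30.2 and 24.8 CPM in Hashtags 6 and 7, and at most 0.747 CPM in the others. CXCL2, a neutrophil chemokine, was at 285 CPM in Hashtag 7, and at 143, 160 and 144 CPM in Hashtags 1, 2 and 6.

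Over the 21 pairs of hashtags, the SD of log2 ratios across genes was lowest for Hashtags 6 and 7, at 0.23, and highest for Hashtags 1 and 5, at 1.11. Another cluster of 112 passing barcodes had a median of 1638 UMIs and 0.553% mitochondrial UMIs, and 21.4% of them had a called hashtag.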
